A study of Mus musculus with 9 samples.

How the data were processed

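RNA-seq of mouse liver was analysed in 9 libraries, 3 each from sham surgery, ischaemia-reperfusion (IR) and ischaemic postconditioning (IPO). Per the labels, the mice were C57BL/6 of 8 weeks, the livers were flash frozen on dry ice, RNA was taken up in Trizol, and libraries were made with the KAPA stranded kit and run on an Illumina HiSeq. The submitters' processing notes name the mm10 build, which was used for all coordinates. The aligner, the annotation and the program that made the values are not given in the sources used here.

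The gene table and the table of unannotated loci hold FPKM (fragments scaled by transcript length and library size), computed by the authors and deposited per library. In the authors' deposited tables of differing genes, the group means are means of log2(FPKM + 1) over 3 libraries and the log2 fold change is their difference. The fold change in those tables is the ratio given by 2 to the power of that difference, as deposited by the authors. The p-value and q-value in those tables come from a test by the authors that is not given in the sources used here, and they were printed but not used. These tables hold listed genes only, so the genes they leave out have no value in them. The locus table also gives a length per locus, which per the file headers is the span in bases. All value columns were matched to a library. An empty line was found 1 time among the gene values, and 9 symbols stood for more than 1 gene identifier and were kept apart by identifier.

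The values are not counts, so depth and counting error are unknown. Of 200 values per library, 33.0% to 37.5% lay near a whole number of reads at the best of the steps tried, against 20% by chance at any 1 step, which does not fix the depth. Library sizes were not rescaled in the chosen analysis.

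Values were transformed to log2(FPKM + 0.5), and genes with a mean of at least 1 FPKM over the 9 libraries were tested, 9649 of 11229. A single limma fit (limma 3.58.1 and R 4.3.3, with values read by version 1.17.8 of the data.table package) held the 3 group means, with a variance trend and without robust estimation, with 6 residual degrees of freedom and a prior of 3.56. The 3 comparisons were tested with two-sided moderated tests. P-values were adjusted by Benjamini-Hochberg within each comparison and called at an adjusted p under 0.05, with no minimum fold. The count with a fold of at least 2 is given beside it. Library summaries were compared by exact permutation, where 3 against 3 gives 10 splits and a smallest p of 0.1. Groups, tests, gene lists and the rule for named genes were set before the data were examined.

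Named genes are, in each comparison, the 10 largest rises and 10 largest falls among called genes with at least 5 FPKM in the higher group and no overlap between groups, leaving out predicted and clone-named genes. The rule also names up to 4 members of each gene list with the smallest p. Some genes that the rule names are not reported here. Genes named for another reason are said to be chosen after their values were seen.

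Gene sets were 42 lists, of which 37 had at least 3 tested members and were tested with limma camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Beside it stand camera with an estimated correlation, fry, and counts of members adjusted over the list alone. Of the 42 lists, 5 had fewer than 3 tested members and were not tested, namely nuclear long non-coding RNAs, T and NK cell markers, B cell markers, pancreas transcripts, and adipose and mesothelial transcripts. Some genes belong to more than 1 list.

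Opposite changes were counted as genes called between IR and sham and called with the other sign between IPO and IR. They were set beside independent lists and beside 100 simulations of unchanged groups that share the IR libraries. They were also set beside 100 groupings of the 9 libraries, the real one included. The unannotated loci were fitted in the same way with their own filter. Gene positions were matched to GENCODE M21, which held 11212 of the 11229 identifiers, 8693 of them with identical start and end. That annotation gave the GC content and length for a loess correction.

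The replicate numbers recur in each group, so pairing was checked before the fits were compared. Over 9 same-numbered pairs of libraries the correlation of residuals ran from -0.137 to 0.0653, and 0 exceeded 0.1. Of the 9 libraries 1 matched best with its own number. No block was used, as set in advance, since nothing in the labels says that replicate numbers pair animals. Alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a replicate block, fits on 2 groups only, robust estimation, the description number as a term, an estimated correlation for lists, and leaving out each library in turn.

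The procedure was tested on simulated data with 200 changed genes among 9649, and recovered 73% of 100 genes changed 2-fold and 97% of 100 changed 4-fold, with 6 unchanged genes called. The simulated noise was normal, independent between genes and of equal size in every group, as the fit assumes. The real libraries need not meet this, so these rates may be too favourable. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not used here, and splicing and sequence variants were not analysed here.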

Results

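RNA from the livers of 8-week-old C57BL/6 mice was sequenced in 3 groups of 3 libraries each. The first group had sham surgery, the second had ischaemia-reperfusion (IR), in which the blood supply of the liver is interrupted and then restored, and the third had ischaemic postconditioning (IPO), in which the restored flow is briefly interrupted again at the start of reperfusion. The labels give neither the length of ischaemia nor the interval between surgery and sampling. They also do not say that the replicates are separate animals, so every p-value measures the spread between these libraries, which may be technical. The gene table held 11229 genes in FPKM, which are fragments scaled by transcript length and library size, and 11178 to 11211 of them were above 0 in each library. The sum of FPKM per library ran from 369625 to 385855 in sham and from 363429 to 379117 in IR, and was at least 375460 in IPO. The number of reads behind the values is unknown, so no counting error is given. Fold changes are on the scale of log2(FPKM + 0.5), which understates the change of genes near 0.

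The IR libraries lay apart from the sham and IPO libraries. The first principal component held 46.8% of the variance and placed the IR libraries at 43.8, 33.4 and 29.8, the IPO libraries at -25.6, -19.5 and -20.3, and the sham libraries at -21.2, -18.2 and -2.20. Sham replicate 3 was thus the sham library nearest to IR, and its mean over the 23 acute phase genes was 8.23 on the log2 scale, against 9.14 and 9.13 in sham replicates 1 and 2. Its mean over the 15 clock genes was 3.17, against 2.40 and 2.60 in the other sham libraries and 3.48, 3.17 and 3.39 in the IR libraries. The second component held 13.8% and set IR replicate 1, at -23.6, against IR replicate 3, at 26.4. Pearson correlations across genes ran from 0.955 to 0.987 within groups, from 0.964 to 0.976 between sham and IPO, from 0.924 to 0.966 between IR and sham, and from 0.917 to 0.943 between IR and IPO. These correlations are across genes, which are not independent replicates. The 10 most abundant genes held 14.4% ± 0.581 (SD, n = 3) of the summed FPKM in sham, 15.7% ± 0.551 in IR and 15.7% ± 0.631 in IPO. For IR and for IPO against sham the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow.

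**Figure D1:**
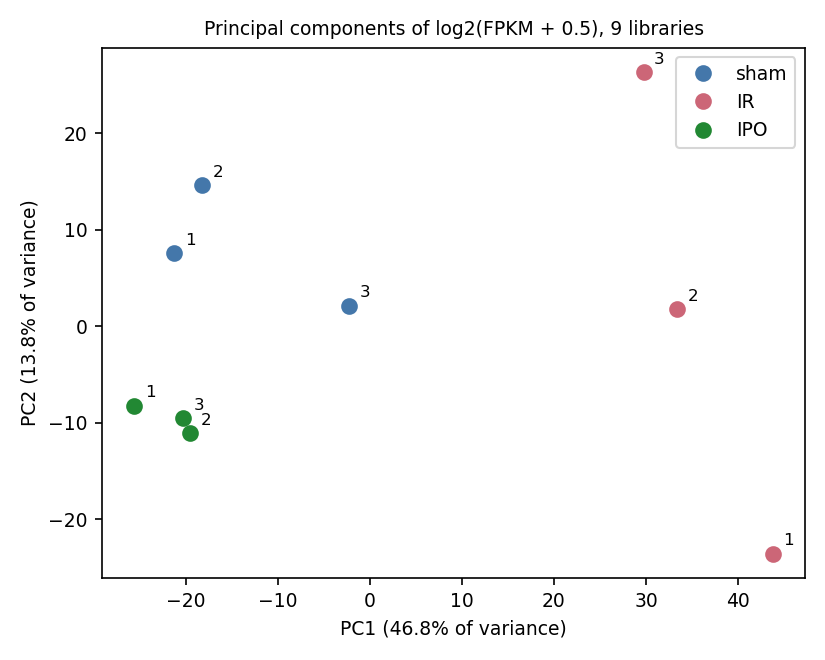
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 0.5) over 9649 genes, coloured by group. The IR libraries lie between 29.8 and 43.8 on the first component and the sham and IPO libraries between -25.6 and -2.20.

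The comparison of IR with sham asked what ischaemia-reperfusion changed in liver. Most tested immediate early genes rose, and most tested acute phase genes fell. The former are induced within minutes by stress and growth signals, and the hepatocyte secretes the products of many, not all, of the latter in inflammation. Fosb (ENSMUSG00000003545.3, chromosome 7, 19302696 to 19310051 on mm10) rose from 0.431 ± 0.675 FPKM (SD, n = 3) in sham to 54.1 ± 7.67 in IR, a log2 fold change of 6.09 (SE 0.44, limma adjusted p = 0.000328). Saa2 (ENSMUSG00000057465.5, chromosome 7, 46751790 to 46754313) fell from 871 ± 432 to 24.7 ± 37.8 FPKM, a log2 fold change of -6.42 (SE 1.03, adjusted p = 0.00709). Lcn2 (ENSMUSG00000026822.14, chromosome 2, 32384633 to 32388252), which encodes lipocalin 2, fell from 236 ± 138 to 6.32 ± 7.55 FPKM, a log2 fold change of -5.47 (SE 0.74, adjusted p = 0.00374). Cyr61 (ENSMUSG00000028195.4, chromosome 3, 145646976 to 145649981), a matricellular protein gene, rose from 1.73 ± 0.893 to 64.3 ± 19.9 FPKM, with a log2 fold change of 4.88 (SE 0.47, adjusted p = 0.00115). Atf3 (ENSMUSG00000026628.13, chromosome 1, 191170296 to 191218039) rose from 6.84 ± 7.01 to 134 ± 25.7 FPKM, with a log2 fold change of 4.62 (SE 0.63, adjusted p = 0.00374). Cyp2b10 (ENSMUSG00000030483.14, chromosome 7, 25897620 to 25926624), a drug-metabolising cytochrome P450, fell from 144 ± 60.5 to 2.81 ± 1.11 FPKM, with a log2 fold change of -5.40 (SE 0.56, adjusted p = 0.00139).

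The other genes among the 10 largest rises were Fos, Pdk4, Nr4a1, Chka, Gdf15, Otud1 and Osgin1, with log2 fold changes from 3.02 for Osgin1 to 4.22 for Fos and adjusted p from 0.000328 to 0.0394. Pdk4, a kinase that restrains glucose oxidation, rose from 13.8 ± 7.76 to 221 ± 126 FPKM, and Gdf15, a stress-induced cytokine, rose from 17.9 ± 12.8 to 146 ± 51.7 FPKM. Fos stood at 11.9 FPKM in IR replicate 1 and at 245 and 291 FPKM in the other IR libraries. Its adjusted p was 0.0989 without IR replicate 2, 0.0771 without IR replicate 3, 0.125 without sham replicate 1, 0.122 without sham replicate 2, 0.0565 without IPO replicate 2 and 0.0621 without IPO replicate 3. Osgin1 had an adjusted p of 0.0592 without sham replicate 2. The other genes among the 10 largest falls were B3galt1, Saa1, Steap4, Tifa, Cxcl1, Orm2 and Slc41a2, with log2 fold changes from -5.42 for B3galt1 to -3.03 for Slc41a2. Cxcl1, a neutrophil attractant, fell from 132 ± 39.7 to 11.3 ± 9.09 FPKM, and Steap4, a metalloreductase, fell from 563 ± 333 to 22.8 ± 13.6 FPKM. Orm2 had an adjusted p of 0.0784 without sham replicate 1, 0.0776 without sham replicate 2 and 0.0601 without IR replicate 1.

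**Figure D2:**
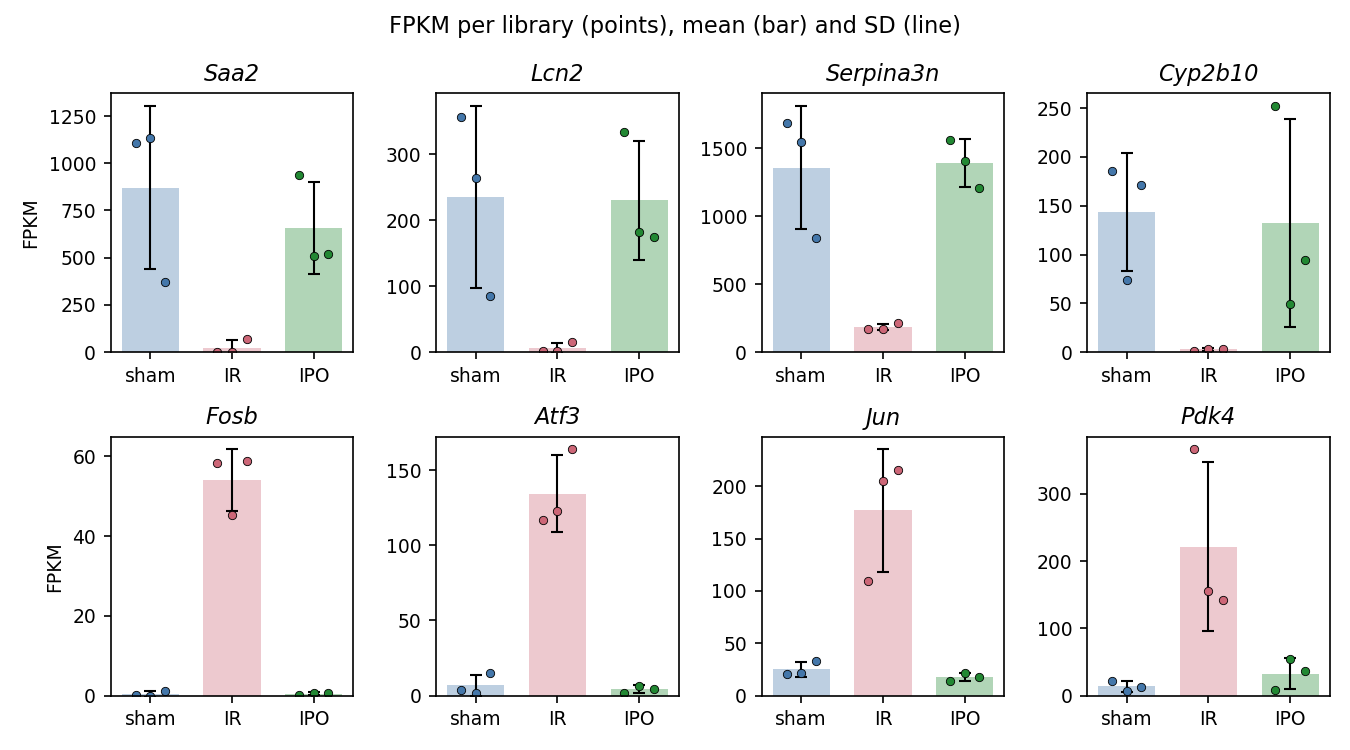
FPKM of 8 named genes in sham, IR and IPO, with a point per library, the mean as a bar and the SD as a line (n = 3, linear axes). Saa2, Lcn2, Serpina3n and Cyp2b10 lie lowest in IR, where Saa2 had a mean of 24.7 FPKM, and Fosb, Atf3, Jun and Pdk4 lie highest, with Fosb at 54.1 FPKM.

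Of the 23 tested acute phase genes, 21 fell in IR, 0 rose and 2 were not past the test, and 23 fell when adjusted over the list alone. The list was lower as a set, with a median log2 fold change of -1.67 (camera adjusted p = 4.02e-16; adjusted p = 0.485 with an estimated correlation). Its members with the smallest p were Serpina3n, Il1r1, Fgb and Fgg. Serpina3n, a protease inhibitor gene, fell from 1359 ± 455 to 186 ± 24.7 FPKM (log2 fold change -2.81, SE 0.25), and the fibrinogen chain genes Fgb and Fgg fell from 1720 ± 196 to 745 ± 68.2 and from 2797 ± 468 to 1051 ± 162 FPKM. The mean of the list over its members on the log2 scale was 8.83 ± 0.525 (SD, n = 3) in sham and 6.49 ± 0.514 in IR, with an exact permutation p of 0.1. The 9 neutrophil marker genes were also lower as a set, with a median of -1.04 (camera adjusted p = 0.00683; adjusted p = 0.609 with an estimated correlation). Of them 2 fell, Lcn2 and Mmp8, 0 rose and 7 were not past the test, and 4 fell when adjusted over the list alone; Clec4d and Cxcr2 came next by p. The mean of the neutrophil list was 0.579 in IR replicate 1, 1.46 in IR replicate 2 and 2.31 in IR replicate 3, and the adjusted p was 0.0583 without IR replicate 1. Lcn2 belongs to both lists and is expressed by hepatocytes as well as neutrophils.

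Of the 16 tested immediate early genes, 13 rose, 0 fell and 3 were not past the test, and 15 rose when adjusted over the list alone. The list was higher as a set, with a median log2 fold change of 2.31 (camera adjusted p = 1.52e-14; adjusted p = 0.485 with an estimated correlation). Ier2 had its smallest p and rose from 16.3 ± 1.12 to 130 ± 12.7 FPKM (log2 fold change 2.96, SE 0.18, adjusted p = 0.000126), and Fosb, Nr4a1 and Jun followed. Jun rose from 25.2 ± 7.01 to 177 ± 58.4 FPKM. Of 15 p53 target and cell death genes, 4 rose, 1 fell and 10 were not past the test, and adjusted over the list alone the counts were again 4 and 1. The median of that list was 0.41 (camera adjusted p = 0.0337; adjusted p = 0.609 with an estimated correlation). Gadd45b rose from 17.4 ± 6.03 to 92.1 ± 19.2 FPKM and Trp53inp1 from 30.7 ± 15.8 to 153 ± 12.5 FPKM, with Bbc3 and Gadd45a also up. The call of the p53 list ended without sham replicate 3 (0.0856), without IR replicate 1 (0.0583), without IR replicate 3 (0.107) and with median-of-ratios scaling (0.0589). It ended too among members with a mean of at least 5 FPKM (0.191), where the median was 0.06, and the median was 0.07 without IR replicate 3.

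Of 15 circadian clock genes, 3 rose, 0 fell and 12 were not past the test, and 6 rose when adjusted over the list alone, with a median of 0.58 (camera adjusted p = 0.000522; adjusted p = 0.521 with an estimated correlation). The clock median was 0.37 without sham replicate 1 and 0.92 without sham replicate 3. Nr1d1, the repressor REV-ERB alpha, rose from 10.3 ± 1.5 to 42.6 ± 8.25 FPKM (log2 fold change 1.99, SE 0.16, adjusted p = 0.000434), and Bhlhe40 and Per1 rose too, while Cry2 had a log2 fold change of 1.18 and an adjusted p of 0.0519. Of 22 fatty acid oxidation and PPARA target genes, 2 rose, Pdk4 and Ppara, 0 fell and 20 were not past the test, and 2 rose when adjusted over the list alone. That list was higher as a set, with a median of 0.34, which was 0.16 with the description number as a term (camera adjusted p = 0.000767; adjusted p = 0.609 with an estimated correlation); Angptl4 and Hadha had the next smallest p. Of 14 periportal hepatocyte genes, 1 rose, Etnppl, from 14.9 ± 2.21 to 44.7 ± 5.29 FPKM, 0 fell and 13 were not past the test. Adjusted over the list alone 7 rose, and the median was 0.39 (camera adjusted p = 0.0038; adjusted p = 0.609 with an estimated correlation), with Hal, Pck1 and Cyp2f2 next by p. None of the 12 pericentral genes passed the test over all genes, and 3 rose when adjusted over the list alone. Their median was 0.28 (camera adjusted p = 0.0393; adjusted p = 0.485 with an estimated correlation), and Aldh3a2, Oat, Gulo and Cyp1a2 had the smallest p. The pericentral call ended without sham replicate 2 (0.0825), without IR replicate 1 (0.0583), without IR replicate 3 (0.0655) and with median-of-ratios scaling (0.0572). Of 22 genes for hepatocyte secreted proteins, 0 passed the test over all genes and 0 when adjusted over the list alone, at a median of 0.17 (camera adjusted p = 0.0117; adjusted p = 0.609 with an estimated correlation). Ttr, Alb, Apoa1 and F2 had their smallest p, and the call ended without sham replicate 2 (0.0825) and without IR replicate 1 (0.0583).

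Sinusoidal endothelial, stellate and Kupffer cell markers were higher as sets, while neutrophil markers were lower and monocyte, platelet and cholangiocyte markers were not called. Of 15 sinusoidal endothelial markers, 4 rose, 1 fell and 10 were not past the test, against 5 and 1 when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.00125; adjusted p = 0.609 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor, rose from 2.50 ± 0.551 to 7.48 ± 1.06 FPKM (log2 fold change 1.42, SE 0.18), and Ehd3, Stab2 and Dnase1l3 rose as well. Of 13 stellate cell and fibroblast markers, 2 rose, Reln and Colec11, 0 fell and 11 were not past the test, and 2 rose when adjusted over the list alone; Lrat and Des came next. The median was 0.53 (camera adjusted p = 0.00341; adjusted p = 0.609 with an estimated correlation), but 0.08 among members with a mean of at least 5 FPKM, where the call ended (0.308). None of the 15 Kupffer cell markers passed the test over all genes or when adjusted over the list alone, and the median was 0.55 (camera adjusted p = 0.0202; adjusted p = 0.762 with an estimated correlation). Cd5l, Csf1r, Cd163 and Clec4f had their smallest p, and the Kupffer call ended without sham replicate 3 (0.0601) and without IR replicate 3 (0.489), where the median was -0.03.

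Single genes passed the test in lists that were not called. Of 18 listed cytochromes P450, 4 fell, Cyp2b10, Cyp3a13, Cyp2c29 and Cyp2c70, 0 rose and 14 were not past the test. Adjusted over the list alone 3 rose and 4 fell (camera adjusted p = 0.773). The median of that list, -0.06, changed sign under both other scalings. The metallothionein genes Mt2 and Mt1 fell from 1934 ± 547 to 404 ± 91.0 and from 2097 ± 595 to 487 ± 107 FPKM, with log2 fold changes of -2.24 and -2.08. In their list, with NRF2 targets, 1 of 15 rose, Osgin1, 3 fell, including Txnrd1, and 11 were not past the test, with the same counts when adjusted over the list alone (camera adjusted p = 0.609; also 0.869 with an estimated correlation). Among 19 transcription factors of the hepatocyte programme 1 rose, Ppara, 4 fell, including Onecut1 and Prox1, and 14 were not past the test, against 2 and 4 when adjusted over the list alone (camera adjusted p = 0.984). Onecut1 fell from 9.07 ± 3.08 to 1.38 ± 0.297 FPKM (log2 fold change -2.31, SE 0.23). In the list of cytokines, chemokines and adhesion molecules 1 of 14 members rose, 2 fell, Cxcl1 and Icam1, and 11 were not past the test. The counts were the same when adjusted over the list alone (camera adjusted p = 0.614). The member that rose was Nfkbia, which encodes an intracellular inhibitor and is none of these molecules. Cxcl2 had a log2 fold change of 2.23 and a limma adjusted p of 0.11. Among 17 unfolded protein and amino acid stress genes Sesn2 and Trib3 rose, Xbp1 fell from 168 ± 47.6 to 52.9 ± 3.16 FPKM, and 14 were not past the test, against 2 and 2 when adjusted over the list alone (camera adjusted p = 0.371); Dnajc3 was next.

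The remaining lists were not called in IR against sham, though some were under an alternative. With quantile normalization the ribosomal protein list was called lower (adjusted p = 0.00245) and the gluconeogenesis list higher (0.0473), and without sham replicate 3 the cholesterol (0.000339), gluconeogenesis (0.000376), bile acid (0.00425), lipogenesis (0.0204), ribosomal (0.028) and coagulation (0.0301) lists were called. Among 16 lipogenesis genes Srebf1, Fads2 and Elovl5 rose and Elovl6 fell, against 4 and 2 when adjusted over the list alone (camera adjusted p = 0.103). Among 20 cholesterol synthesis genes 2 rose, including Insig1, and 18 were not past the test, with 2 up also when adjusted over the list alone (camera adjusted p = 0.208). G6pc rose from 72.4 ± 50.8 to 280 ± 59.0 FPKM and was the 1 call among 18 genes of gluconeogenesis and amino acid catabolism, over all genes and when adjusted over the list alone (camera adjusted p = 0.0547). Abcb4 was the 1 call, upwards, among 14 bile acid genes, and 2 rose when adjusted over the list alone (camera adjusted p = 0.0567), with Cyp8b1, Cyp7a1 and Slc27a5 next. Elovl3 and Hsd3b5 rose among 14 sex-linked and sex-biased genes, with the same 2 when adjusted over the list alone (camera adjusted p = 0.371). Stat2 fell among 14 interferon response genes (camera adjusted p = 0.322), Onecut1 fell among 6 cholangiocyte markers (camera adjusted p = 0.93), and Cyr61 rose among 8 genes of transforming growth factor, fibrosis and matrix remodelling (camera adjusted p = 0.295), each the only call also when adjusted over the list alone. Atg16l1 fell among 15 autophagy genes, with 0 calls when adjusted over the list alone (camera adjusted p = 0.866). No member passed the limma test over all genes for erythroid transcripts (camera adjusted p = 0.0583), ribosomal proteins (0.0594), smooth muscle, gallbladder and gut transcripts (0.103), coagulation and fibrinolysis (0.117), heat shock chaperones (0.206), mitochondrially encoded transcripts (0.284), hypoxia and glycolysis (0.322), nuclear-encoded oxidative phosphorylation (0.594), cell cycle (0.758), monocyte and infiltrating macrophage markers (0.866) and platelet and megakaryocyte transcripts (0.974). Of these, the smooth muscle list had 2 rises when adjusted over the list alone and the others 0, and the oxidative phosphorylation median of -0.003 changed sign with median-of-ratios scaling.

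In all, 1109 of 9649 tested genes passed limma at an adjusted p under 0.05 in IR against sham, of which 372 rose and 737 fell, and 379 also changed at least 2-fold (143 up, 236 down). The IR and sham values did not overlap for 32.5% of tested genes, where chance gives 10%. Of 37 lists 12 were called, 10 higher and 2 lower. With an estimated correlation camera called 0 lists, at a lowest adjusted p of 0.485, while 8 were called by fry, which asks only whether a list moves one way. These were 5 of the 12 (acute phase, immediate early, clock, periportal and pericentral) and 3 that camera did not call (hepatocyte transcription factors, lower, and smooth muscle and fibrosis lists, higher). The transcription factor median was 0.02, with 10 of 19 members at a positive fold change, and the fibrosis median 0.04, with 4 of 8. Neither of these lists thus moved as a whole. Of the 10 ways to split these 6 libraries 3 against 3, 6 gave at least 12 called lists, and the highest other count was 15, so the list calls do not set the groups apart from other splits. The count of genes was 310 without sham replicate 2 and nearly as low without sham replicate 1. It was 653 without IR replicate 1, 678 without IR replicate 2, 713 without IPO replicate 2 and 620 without IPO replicate 3, since the IPO libraries share in the estimate of spread. It was 1361 without sham replicate 3, and 341 in a fit on sham and IR only, which leaves out the IPO libraries. Of the 68 named genes called in this comparison, 23 lost the call without sham replicate 1 and 22 without sham replicate 2, and none changed sign.

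The descriptions of the libraries hold a number whose meaning is not stated. Sham replicate 2 shares it with all IR libraries, sham replicates 1 and 3 share another, and all IPO libraries have one of their own. With that number as a term in a fit of sham and IR only, 6 genes passed limma (Fosb, Nr4a1, Cyr61, Ier2 and Gm20708 up, Cyp2b10 down; the last of the rises lies outside the rule for named genes and is listed after its values were seen), and 1441 had an unadjusted p under 0.05. The estimate in that fit equals the IR mean minus sham replicate 2, so it rests on 1 sham library. That difference was -6.97 for Saa2, -5.67 for Saa1, -5.87 for Lcn2 and -4.56 for Cyp2b10. It was 6.65 for Fosb, 5.75 for Atf3, 5.10 for Cyr61 and 4.77 for Pdk4. These genes were taken from the largest changes, which by rule have no overlap between the sham and IR libraries. The signs of these differences were thus fixed in advance, and they do not show that the changes are independent of the number. In IPO the number is the same for every library, so number and group cannot be told apart there.

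The comparison of IPO with IR asked what postconditioning changed against ischaemia-reperfusion alone. The genes with the largest changes were mostly those of the comparison above, with the opposite sign. Saa2 rose from 24.7 ± 37.8 FPKM (SD, n = 3) in IR to 656 ± 244 in IPO, a log2 fold change of 6.12 (SE 1.03, limma adjusted p = 0.00463). Lcn2 rose from 6.32 ± 7.55 to 230 ± 90.2 FPKM, a log2 fold change of 5.60 (SE 0.74, adjusted p = 0.00161), and Cyp2b10 rose from 2.81 ± 1.11 to 132 ± 107 FPKM, a log2 fold change of 5.07 (SE 0.56, adjusted p = 0.000834). Fosb fell from 54.1 ± 7.67 to 0.504 ± 0.362 FPKM, a log2 fold change of -5.83 (SE 0.44, adjusted p = 0.000216). Ier2 (ENSMUSG00000053560.4, chromosome 8, 84661331 to 84662852 on mm10) fell from 130 ± 12.7 to 11.7 ± 2.94 FPKM, a log2 fold change of -3.45 (SE 0.18, adjusted p = 5.99e-05). The other genes among the 10 largest rises were Saa1, B3galt1, Steap4, Syt12, Tifa, Serpina7 and Cldn14, at 3.52 to 4.87. Serpina7 (ENSMUSG00000031271.14, chromosome X, 139079257 to 139085236), which encodes thyroxine-binding globulin, rose from 2.37 ± 1.77 to 32.4 ± 18.3 FPKM and stood at 8.14 ± 1.43 in sham. The other genes among the 10 largest falls were Atf3, Fos, Cyr61, Nr4a1, Kcnk5, Osgin1, Jun and Egr1, at -4.99 to -3.19. Fos had an adjusted p of 0.0519 without IR replicate 2 and 0.0624 without IPO replicate 1.

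Of the 23 acute phase genes, 18 rose in IPO against IR, 0 fell and 5 were not past the test, and 20 rose when adjusted over the list alone, with a median of 1.51 (camera adjusted p = 5.91e-12; adjusted p = 0.455 with an estimated correlation). Serpina3n rose from 186 ± 24.7 to 1394 ± 178 FPKM (log2 fold change 2.90, SE 0.25, adjusted p = 0.000305), and Fgb, Il1r1 and Fgg followed. Of the 9 neutrophil markers, 5 rose, including Lcn2, Clec4d, Il1r2 and Cxcr2, 0 fell and 4 were not past the test, and 7 rose when adjusted over the list alone, with a median of 1.54 (camera adjusted p = 0.00311; adjusted p = 0.638 with an estimated correlation). Mt2 rose from 404 ± 91.0 to 2420 ± 34.6 FPKM and Mt1 from 487 ± 107 to 2572 ± 89.0 FPKM. In the list of metallothioneins and NRF2 targets 5 of 15 rose, 1 fell, Osgin1, and 9 were not past the test, against 6 and 1 when adjusted over the list alone, with Txnrd1 next by p. Its median was 0.38 (camera adjusted p = 0.0481; adjusted p = 0.614 with an estimated correlation), and the call ended without sham replicate 1 (0.0691), IR replicate 1 (0.123), IR replicate 2 (0.065) or IPO replicate 3 (0.0681). It also ended with a pseudocount of 0.1 (0.0531), a replicate block (0.0544) or a fit on 2 groups only (0.0623). Of 22 ribosomal protein genes 1 rose, Rps27a, 0 fell and 21 were not past the test, and 0 passed when adjusted over the list alone. The ribosomal median was 0.25 (camera adjusted p = 0.00777; adjusted p = 0.677 with an estimated correlation), with an adjusted p of 0.0681 without IPO replicate 3; Rps6, Rpl5 and Rpl10 came next. None of the 13 mitochondrially encoded transcripts passed the test over all genes or when adjusted over the list alone, and mt-Nd4l, mt-Atp8, mt-Nd3 and mt-Nd5 had the smallest p. Their median was 0.35 (camera adjusted p = 0.0179; adjusted p = 0.677 with an estimated correlation). That call ended without IR replicate 1 (0.119), whose mean over the list was 10.8 against 11.4 and 11.7 in the other IR libraries, without IPO replicate 3 (0.0504) and with quantile normalization (0.283).

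Of the 16 immediate early genes, 14 fell in IPO against IR, 0 rose and 2 were not past the test, with 14 also when adjusted over the list alone, at a median of -2.26 (camera adjusted p = 3.83e-11; adjusted p = 0.455 with an estimated correlation); Ier2, Nr4a1, Fosb and Jun had the smallest p. Of 22 fatty acid oxidation and PPARA target genes, 17 fell, 0 rose and 5 were not past the test, and 19 fell when adjusted over the list alone. Their median was -0.73 (camera adjusted p = 6.86e-08; adjusted p = 0.614 with an estimated correlation). Ppara fell from 34.5 ± 8.25 to 15.1 ± 0.794 FPKM, and Hadha and Cpt2 fell too. Of 15 clock genes 7 fell, 0 rose and 8 were not past the test, and 9 fell when adjusted over the list alone, with a median of -1.03 (camera adjusted p = 0.000125; adjusted p = 0.455 with an estimated correlation). Nr1d1 fell from 42.6 ± 8.25 to 16.4 ± 0.700 FPKM, and Bhlhe40 and Arntl also fell. Of 15 heat shock chaperone genes 6 fell, 0 rose and 9 were not past the test, and 8 fell when adjusted over the list alone, with a median of -0.55 (camera adjusted p = 0.00285; adjusted p = 0.638 with an estimated correlation). Hspa1a fell from 9.50 ± 2.79 to 1.36 ± 0.387 FPKM and Hspa1b from 31.3 ± 15.5 to 4.46 ± 1.5 FPKM, near-identical copies whose reads may be shared, and Hsph1 and Dnajb1 fell as well.

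Of 18 genes of gluconeogenesis and amino acid catabolism 6 fell, including G6pc, Pck1, Fbp1 and Hal, 1 rose and 11 were not past the test, against 7 and 1 when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.0056; adjusted p = 0.638 with an estimated correlation). G6pc fell from 280 ± 59.0 to 47.4 ± 17.7 FPKM. Of 14 periportal genes 5 fell, including Etnppl, Pck1, Gls2 and Hal, 1 rose and 8 were not past the test, against 6 and 1 when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.00777; adjusted p = 0.614 with an estimated correlation). Of 12 pericentral genes 4 fell, Aldh3a2, Oat, Slc22a3 and Rhbg, 0 rose and 8 were not past the test, and 5 fell when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.00777; adjusted p = 0.455 with an estimated correlation). Of 15 sinusoidal endothelial markers 3 fell, Kdr, Ehd3 and Dnase1l3, 1 rose, Lyve1, and 11 were not past the test, against 5 and 1 when adjusted over the list alone. The sinusoidal median was -0.46 (camera adjusted p = 0.0145; adjusted p = 0.677 with an estimated correlation; 0.0855 without IR replicate 3). Of 5 erythroid transcripts 1 fell, Alas2, and 4 were not past the test, and 2 fell when adjusted over the list alone, with a median of -0.80 (camera adjusted p = 0.0357; adjusted p = 0.638 with an estimated correlation); Hba-a2, Hba-a1 and Hbb-bt came next. The erythroid call ended without IR replicate 3 (0.0882), without IPO replicate 1 (0.0649) and with quantile normalization (0.052).

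Among lists not called in IPO against IR, several genes of hepatocyte function passed the test. Cyp2c70 rose from 52.0 ± 4.98 to 260 ± 78.3 FPKM and Cyp2c29 from 165 ± 55.7 to 639 ± 130 FPKM, and 4 of 18 cytochromes P450 rose, 2 fell and 12 were not past the test, against 5 and 4 when adjusted over the list alone (camera adjusted p = 0.731). Cyp8b1 fell from 382 ± 144 to 119 ± 33.9 FPKM, and 4 of 14 bile acid genes fell, including Abcb4, Nr0b2 and Cyp7a1, with 1 up, and the same counts when adjusted over the list alone (camera adjusted p = 0.14). Of 19 hepatocyte transcription factors 3 rose, including Onecut1, and 6 fell, including Cebpa, Ppara and Esrra, against 4 and 6 when adjusted over the list alone (camera adjusted p = 0.698). Gadd45b, Bbc3, Gadd45a and Trp53inp1 fell among 15 p53 target and cell death genes, the same 4 counted when adjusted over the list alone (camera adjusted p = 0.14). Of 17 unfolded protein and amino acid stress genes 5 fell, including Sesn2, Herpud1 and Ddit3, and 1 rose, Xbp1, with the same counts when adjusted over the list alone (camera adjusted p = 0.218). Of 20 cholesterol synthesis genes 2 rose, including Sqle, and 1 rose when adjusted over the list alone (camera adjusted p = 0.505). Of 16 lipogenesis genes 3 rose, including Acaca, and 3 fell, Fads2, Elovl5 and Gpam, with the same counts when adjusted over the list alone (camera adjusted p = 0.213). Cd14 and Chil3 rose among 8 monocyte markers, as when adjusted over the list alone (camera adjusted p = 0.14). Nfkbia, itself not a cytokine, fell and Cxcl1 rose among 14 members of the cytokine list, as when adjusted over the list alone (camera adjusted p = 0.892).

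The other lists not called in IPO against IR held few calls. Onecut1 rose and 2 genes fell, including Sox9, among 6 cholangiocyte markers, with 1 up and 3 down when adjusted over the list alone (camera adjusted p = 0.731). Optn and Atg5 fell and Map1lc3b rose among 15 autophagy genes, as when adjusted over the list alone (camera adjusted p = 0.257). Elovl3 and Cyp2d9 fell among 14 sex-linked and sex-biased genes, as when adjusted over the list alone (camera adjusted p = 0.528). Cyr61 fell and Plaur rose among 8 genes of transforming growth factor, fibrosis and matrix remodelling (camera adjusted p = 0.892), Plaur rose among 19 coagulation and fibrinolysis genes (0.347), Vegfa fell among 15 hypoxia and glycolysis genes (0.197), and Lgals4 fell among 3 smooth muscle, gallbladder and gut transcripts (0.0836), with the same calls when adjusted over the list alone. Stat2 rose among 14 interferon genes (camera adjusted p = 0.426) and Colec11 fell among 13 stellate markers (0.0836), with 0 calls in either when adjusted over the list alone. No member passed limma, over all genes or when adjusted over the list alone, for Kupffer cell markers (camera adjusted p = 0.155), oxidative phosphorylation (0.206), cell cycle (0.257), hepatocyte secreted proteins (0.428) and platelet transcripts (0.854).

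Between IPO and IR, 2133 of 9649 genes passed limma, of which 1154 rose and 979 fell, and 626 also changed at least 2-fold (355 up, 271 down). The values did not overlap for 42.7% of tested genes against 10% by chance. Of 37 lists 14 were called, 5 higher and 9 lower, while camera with an estimated correlation called 0, at a lowest adjusted p of 0.455, and fry called 9. These were 7 of the 14 (acute phase, immediate early, metallothionein, fatty acid oxidation, pericentral, periportal and clock) and 2 that camera did not call (hypoxia and smooth muscle lists, lower). The highest count of lists in another split of the 6 libraries was 17. The count of genes was 1085 without IPO replicate 1, 1202 without IPO replicate 2 and 1106 without IPO replicate 3. Of the 98 named genes called here, 27 lost the call without IPO replicate 3, 25 without IPO replicate 1 and 24 without IPO replicate 2, and none changed sign.

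Most genes that differed between IR and sham differed with the opposite sign between IPO and IR. Fosb, Atf3 and Cyr61 rose in IR and fell in IPO, and Saa2, Lcn2 and Cyp2b10 fell in IR and rose in IPO. Such opposite changes were found for 863 genes, 77.8% of the 1109, with 288 up then down and 575 down then up, and 1 gene was called in both with the same sign. Independent lists of these sizes would share 37.7 and 88.1 genes. Both comparisons use the IR libraries, which alone gives opposite signs. Unchanged groups simulated 100 times around shared libraries gave 0.02 such genes on average and 2 at most. No gene differed in that simulation, so few could be called. Its count thus cannot show how many opposite calls the sharing adds among genes that do differ. Across genes the fold changes had a Pearson r of -0.83, against -0.50 in the simulation, and a covariance of -0.271 against -0.0263, a difference of -0.244. The simulation gave each gene the same spread in every group. The median SD within groups was 0.232 in IR, 0.182 in sham and 0.144 in IPO on the log2 scale. With a wider spread in IR, sharing alone can give a more negative r and covariance than simulated. The simulated values against sham below rest on the same assumption. Part of the excess in genes may come from the shared libraries. The fold changes of IR and of IPO against sham had an r of 0.10, against 0.50 simulated, and a covariance that differed from the simulated one by -0.00751. The count of opposite changes was 285 without sham replicate 1, 291 without sham replicate 2, 548 without IR replicate 1, 540 without IR replicate 2, 513 without IPO replicate 1, 522 without IPO replicate 2 and 449 without IPO replicate 3.

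**Figure D3:**
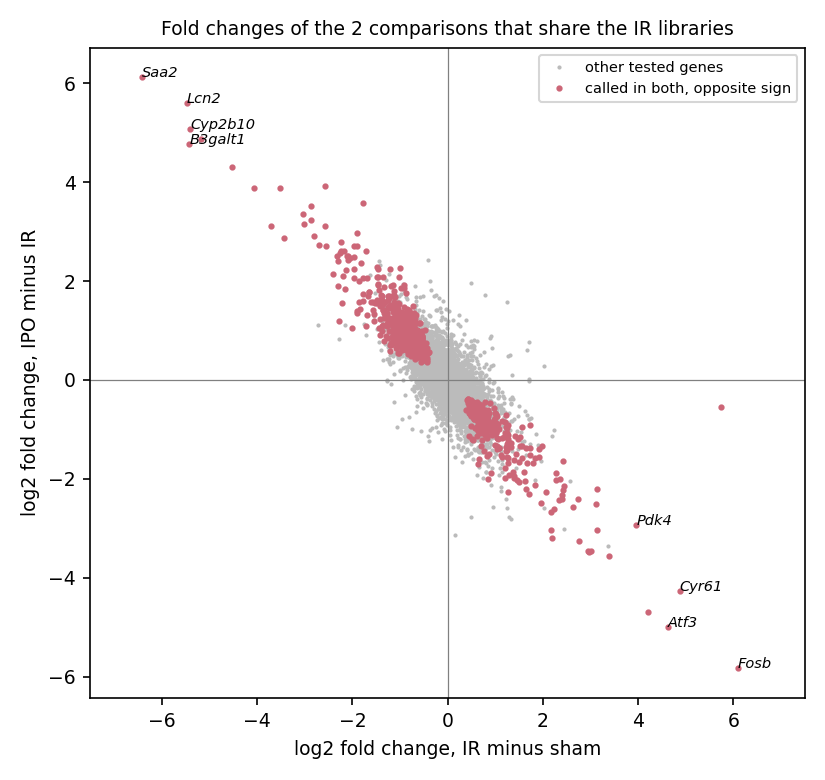
Log2 fold change of IPO minus IR against that of IR minus sham for the 9649 tested genes. The 863 genes called in both with opposite sign are coloured, and the r over all genes is -0.83. Unchanged groups simulated around shared IR libraries gave -0.50, with the same spread assumed in every group.

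The comparison of IPO with sham asked what still differed from sham under postconditioning. Few genes passed the test, which does not show that the others were unchanged. Tubb6 (ENSMUSG00000001473.6, chromosome 18, 67390717 to 67402748 on mm10), a beta-tubulin gene, rose from 4.24 ± 0.755 FPKM (SD, n = 3) in sham to 33.4 ± 6.81 in IPO, a log2 fold change of 2.83 (SE 0.36, limma adjusted p = 0.0209). Tnfrsf12a (ENSMUSG00000023905.14, chromosome 17, 23675447 to 23677449), the receptor of the cytokine TWEAK, rose from 13 ± 2.05 to 79.9 ± 30.0 FPKM, a log2 fold change of 2.50 (SE 0.33, adjusted p = 0.0233). Aqp8 (ENSMUSG00000030762.11, chromosome 7, 123462291 to 123468004), a water channel gene, rose from 5.17 ± 1.67 to 27.1 ± 9.20 FPKM, a log2 fold change of 2.27 (SE 0.31, adjusted p = 0.027). Tmem70 (ENSMUSG00000025940.6, chromosome 1, 16665207 to 16678275), needed to assemble mitochondrial ATP synthase, fell from 26.3 ± 3.88 to 8.40 ± 0.613 FPKM, a log2 fold change of -1.58 (SE 0.16, adjusted p = 0.00931). The other rises named by rule were Adck4, Wdfy1, Cyp2c70, Fndc4, Efhd2, Stom and Nudt4, at 0.79 to 1.49, and the other falls were Afmid, Asic5, Bcl9l, Atoh8, Csk and L3hypdh, at -1.57 to -0.94. IR stood at 12.1 ± 7.21 FPKM for Tubb6, 23.8 ± 9.12 for Tnfrsf12a, 17.5 ± 5.09 for Aqp8 and 17.8 ± 2.80 for Tmem70. Outside the rule, and chosen after their values were seen, Gm20708 and Akr1b7 rose (5.21 and 2.02) and Rtn4rl1, Zfp395 and Bcat2 fell (-1.35, -1.18 and -0.97).

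In all, 22 of 9649 genes passed limma between IPO and sham, 12 up and 10 down, and 18 also changed at least 2-fold (11 up, 7 down), while 1186 had an unadjusted p under 0.05. The values did not overlap for 22.7% of tested genes against 10% by chance. More genes may differ between IPO and sham than were called, but this share does not settle it. It was not computed for other splits of these libraries, and genes that vary together can move it away from 10%. The count was 6 without sham replicate 1, 1 without sham replicate 2, 11 without sham replicate 3, 11 without IR replicate 2, 8 without IPO replicate 1, 6 without IPO replicate 2 and 1 without IPO replicate 3. Each of the 17 named genes called here lost the call without sham replicate 2 and without IPO replicate 3. For Tmem70 the adjusted p was then 0.0531 and 0.0551, and for Tubb6 0.108 and 0.0993. With a replicate block 16 of the 17 lost the call, with an adjusted p of 0.0714 for Tubb6 and Tnfrsf12a and 0.0572 for Tmem70 and Afmid, and 2 genes were called in all.

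Of 37 lists 9 were called between IPO and sham, 7 higher and 2 lower, none of them through members that passed the test over all genes. The 22 fatty acid oxidation and PPARA target genes were lower as a set, with a median of -0.37 (camera adjusted p = 0.000168; adjusted p = 0.825 with an estimated correlation). Adjusted over the list alone 1 fell, and Cpt2, Vnn1, Cyp4a14 and Acot1 had the smallest p; Cyp4a14 stood at 1504 ± 216 FPKM in sham and 760 ± 360 in IPO. The 15 heat shock chaperone genes were lower, with a median of -0.38, which was -0.19 without sham replicate 2 and -0.58 without sham replicate 1, led by Hsph1, Hspa1b, Hspa1a and Chordc1 (camera adjusted p = 0.000747; adjusted p = 0.724 with an estimated correlation), and 0 passed when adjusted over the list alone. The 20 cholesterol synthesis genes were higher as a set, with 16 members above sham and Sc5d among the members with the smallest p. Their median was 0.62, with 0 past the test when adjusted over the list alone (camera adjusted p = 0.00141, and 0.886 with an estimated correlation). Their mean on the log2 scale was 3.77 in sham replicate 3 and 2.76 and 2.38 in the other sham libraries, and the call ended without sham replicate 1 (0.0581), without sham replicate 2 (0.115) and without IPO replicate 1 (0.145). The 15 metallothionein and NRF2 target genes were higher as a set, with 10 members above sham. Their median was 0.20, with 1 rise when adjusted over the list alone (camera adjusted p = 0.0221, 0.597 with an estimated correlation and 0.0576 without IPO replicate 3). Gclc, the catalytic subunit of glutamate-cysteine ligase, stood at 43.2 ± 10.7 FPKM in sham and 150 ± 61.7 in IPO (adjusted p = 0.0796), and Srxn1, Hmox1 and Gsta1 came next.

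The 14 interferon response genes were higher as a set in IPO than in sham, with 10 members above sham. Their median was 0.52, with 2 rises when adjusted over the list alone (camera adjusted p = 0.0314, and 0.886 with an estimated correlation). Rsad2, Ifit1, Stat2, itself at -0.44, and Oasl1 had the smallest p. The 8 tested monocyte and infiltrating macrophage markers, of 16 listed, were higher as a set (camera adjusted p = 0.0314, and 0.597 with an estimated correlation). Their median was 0.61, with 0 rises when adjusted over the list alone, and Spp1, Lgals3, Cd14 and Fn1 led. Spp1 also belongs to the cholangiocyte list and Fn1 to the fibrosis list, so the call does not show monocyte infiltration. The 3 tested cell cycle genes, Ccnd1, Pcna and Rrm2, had a median of 0.64 and 1 rise when adjusted over the list alone (camera adjusted p = 0.0353; adjusted p = 0.597 with an estimated correlation). The 22 hepatocyte secreted protein genes, led by C8a, Ttr, Apob and Apoa2, had a median of 0.09 (camera adjusted p = 0.0353; adjusted p = 0.886 with an estimated correlation), and the 13 mitochondrially encoded transcripts, led by mt-Co1, mt-Nd5, mt-Nd4l and mt-Atp6, a median of 0.14 (camera adjusted p = 0.0366; adjusted p = 0.886 with an estimated correlation), with 0 past the test in either when adjusted over the list alone. The interferon call ended without sham replicate 1 (0.0796), sham replicate 2 (0.0533), IR replicate 1 (0.0603) or IPO replicate 3 (0.0702), and the monocyte call without sham replicate 2 (0.0533), IPO replicate 2 (0.102) or IPO replicate 3 (0.0576). The cell cycle call ended without sham replicate 1 (0.0895), sham replicate 2 (0.067), IPO replicate 1 (0.0685) or IPO replicate 3 (0.0702). Without the filter on low values 9 cell cycle genes were tested, and their median was -0.12 (adjusted p = 0.429). The secreted protein call ended without sham replicate 1 (0.229), sham replicate 2 (0.219), IPO replicate 1 (0.145) or IPO replicate 3 (0.0576) and with quantile normalization (0.134), and the mitochondrial call without sham replicate 1 (0.0895), sham replicate 2 (0.067), IPO replicate 1 (0.145) or IPO replicate 3 (0.134) and with quantile normalization (0.356). The count of called lists was 5 without sham replicate 1, 5 without sham replicate 2 and 3 without IPO replicate 3. With an estimated correlation camera called 0 lists, at a lowest adjusted p of 0.597, and fry called none of the 9, its 1 call being the hepatocyte transcription factors, lower (adjusted p = 0.0196). The highest count of lists in another split of the 6 libraries was 15, and 9 of the 10 splits gave at least 9.

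The acute phase and immediate early lists were not called between IPO and sham, at medians of -0.08 and -0.23 (camera adjusted p = 0.835 and 0.567), with 0 members past the test over all genes or when adjusted over the list alone. Without sham replicate 3 the acute phase list was called lower, at a median of -0.37 (adjusted p = 0.0343). Lbp, Saa4, Orm3 and Fgb had the smallest p of the former and Klf6, Ier2, Btg2 and Egr1 of the latter. Cyp2c70 was the 1 call among 18 cytochromes P450, over all genes and when adjusted over the list alone, and stood at 105 ± 12.1 FPKM in sham and 260 ± 78.3 in IPO (camera adjusted p = 0.925). No member of the other 25 lists passed limma over all genes, and their camera adjusted p ran from 0.095 to 0.969. Adjusted over the list alone, 4 autophagy genes led by Atg16l1, 3 hepatocyte transcription factors led by Esrra, and Tdo2 and Slc22a3 fell and Hsd3b5 rose, while of the clock genes 1 rose, Nr1d1, and 1 fell.

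**Figure D4:**
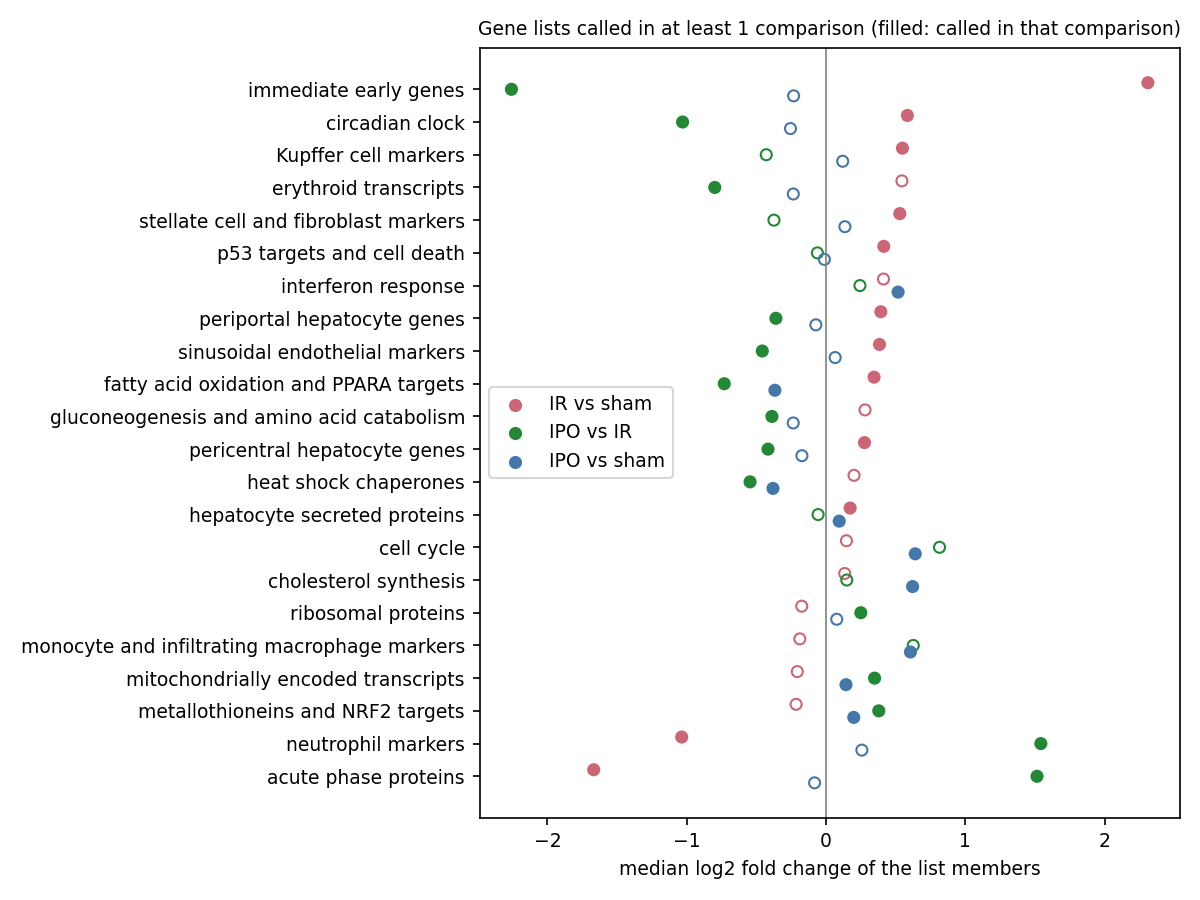
Median log2 fold change of the members of each gene list called in at least 1 comparison, by comparison, with filled points where the list was called. The acute phase list lies at -1.67 in IR against sham and at 1.51 in IPO against IR, and the immediate early list at 2.31 and -2.26.

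The 8 genes called in both IR and IPO against sham, listed after their values were seen, included 4 that changed the same way. Aqp8 rose and Tmem70 and Afmid fell in both, and Gm20708 (ENSMUSG00000093485.1, chromosome 11, 117809668 to 117839904 on mm10) rose from 0.501 ± 0.139 FPKM (SD, n = 3) in sham to 53.7 ± 9.90 in IR and 36.4 ± 3.88 in IPO. Csk, Atoh8 and Bcl9l rose in IR and fell in IPO, and Cyp2c70 fell in IR and rose in IPO. The Gm20708 model spans the models of Syngr2 (117809668 to 117814283) and Afmid (ENSMUSG00000017718.15, 117825924 to 117839908) on the same strand, so reads cannot be assigned to 1 model with certainty. Afmid, which encodes kynurenine formamidase, fell from 35.3 ± 6.17 FPKM in sham to 15.9 ± 2.29 in IR and 11.5 ± 1.28 in IPO, with log2 fold changes of -1.12 and -1.57, and Syngr2 stood at 11.1 ± 7.17, 10.8 ± 3.78 and 8.34 ± 1.94 FPKM. Between IPO and sham the adjusted p of Afmid was 0.0579 without sham replicate 2 and 0.0598 without IPO replicate 3.

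The authors' deposited table of IR against sham listed 320 higher and 567 lower genes, each at a fold of at least 1.5 and a p under 0.05, with the authors' own q-value under 0.05 for 5 and 3 of them. For IPO against IR the authors' deposited table listed 853 higher and 676 lower genes, with a q-value under 0.05 for 326 and 210. For IPO against sham the authors' deposited table listed 148 higher and 127 lower genes, with a q-value under 0.05 for 1 and 0. Of the genes called here, the authors' deposited tables listed 255 of 372 higher and 514 of 737 lower genes between IR and sham, and 769 of 1154 and 584 of 979 between IPO and IR. Between IPO and sham the authors' deposited tables listed all 12 higher and all 10 lower genes.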

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

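The tests of the 4 single loci, of exchanged labels, of time of day, of reads moved between models, of the description number for Gm20708, and of a wrong label or a mixture for sham replicate 3 were chosen only after the result was seen. The criteria for reads moved, Nnt, the wrong label and the mixture were also changed after their values were seen; the judgements on reads moved and on the mixture became open, and the others stayed the same.

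As sets, acute phase genes were lower and immediate early genes higher in IR than in sham and IPO. A bias of GC content or gene length is argued against, since after correction the medians were -1.49 and 2.20 (before it -1.67 and 2.31), with 21 and 13 members still past the test. An exchange of the sham and IR labels as a whole would leave IPO near the libraries labelled sham, as was found with 22 genes called, so it stays open. Another interval after surgery or time of day could also contribute, since the labels give no time. The clock test says little here, since 3 of 15 clock genes were called, but so were 1109 of all 9649 tested genes.

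Gm20708 was higher and Afmid lower in IR and in IPO than in sham. Reads may have moved between the overlapping models, and this stays open, since the summed FPKM of the 3 models was 1.72 times that of sham in IR and 1.20 times in IPO (1.49 and 1.04 when weighted by length). A J against N substrain difference is argued against on its predicted size of 1, since Nnt differed by 0.46 (SE 0.19) in IR and -0.14 (SE 0.19) in IPO, though the 0.46 is not clearly under the lower bound of 0.5 that was written first. If the number that sham replicate 2 shares with the IR libraries marked a batch behind this, Gm20708 would be high in that library. It stood at 0.660 FPKM there, and at 42.8, 62.1 and 56.3 FPKM in the IR libraries. This goes against such a batch in IR but rests on 1 library, so a batch is not excluded. In IPO the number and the group cannot be told apart.

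Sham replicate 3 lay between the other sham libraries and the IR libraries. An IR liver under a wrong label is argued against but not excluded. The median position of sham replicate 3 from sham (0) to IR (1) over 1361 genes was 0.427 (quartiles 0.224 to 0.661). These genes were called between the libraries that define 0 and 1, which can widen that gap. No IR library was placed in the same way, so the position of a true IR liver was not measured. RNA of an IR liver mixed into sham replicate 3 stays open. The linear position was 0.521 (quartiles 0.312 to 0.713) in genes lower and 0.352 (quartiles 0.104 to 0.677) in genes higher in IR, a difference of 0.169. The profile of the library before any mixing is not measured. Another time of day at sampling stays open, since the labels give no time and the test says little: 14 of 15 clock genes lay outside the range of the other sham libraries, but so did 77.0% of all tested genes, and chance gives 66.7%.

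Among 5779 tested loci outside the annotation used by the authors, 730 were called between IR and sham (191 up, 539 down), 1154 between IPO and IR (690 up, 464 down) and 10 between IPO and sham (7 up, 3 down). Most of these lie in known genes, since 541 of 730, 926 of 1154 and 9 of 10 overlapped a gene on the same strand. Only 106, 141 and 1 overlapped no gene on either strand, as did 606 of the 5779 tested. The 4 loci named here were chosen after their values were seen. A locus on chromosome 8 (94396191 to 94396434, mm10), 814 bases from Herpud1, rose by 2.05 on the log2 scale (SE 0.34, limma adjusted p = 0.0069), and one on chromosome 2 (22744825 to 22745037) rose by 2.03 (SE 0.55, adjusted p = 0.0422). A locus on chromosome Y (58848693 to 58855482) changed by -3.61 (SE 0.57, adjusted p = 0.00585), and one on chromosome 5 (137891854 to 137892124), 808 bases from Cyp3a13, changed by -2.39 (SE 0.23, adjusted p = 0.00132).

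Each 3 against 3 comparison has 10 splits, too few for a share under 0.05, so grouping by chance is left open for genes, lists and loci. For genes the real count was 1109 against a highest other of 1 in IR against sham, 2133 against 1 in IPO against IR, and 22 against 3 in IPO against sham, and 1 split, the real one, was as large each time. For loci it was 730 against 2, 1154 against 1 and 10 against 1, again with 1 split as large. For lists it was 12 against 15, 14 against 17 and 9 against 15, with 6, 4 and 9 splits as large, so called lists were as frequent under other groupings. For opposite changes the real count was 863 against 638, with 1 of 100 groupings as large, and the grouping with 638 kept the 3 IR libraries together. No further drawn grouping did so, and the highest count among those was 19. The share thus shows that the IR libraries differ from the rest. It does not show whether opposite changes exceed what that difference alone gives.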

How the results depend on the processing

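None of the tests in this section was chosen only after the result was seen. With a mean of at least 5 FPKM, 5277 genes were tested, and the counts were 650 genes in IR against sham, 1229 in IPO against IR, 510 opposite changes, and 417 and 688 loci; fewer genes were tested by construction. With a replicate block the counts were 646 in IR against sham, 2 in IPO against sham and 538 opposite changes, and the cause was not tested. A fit on 2 groups only called 341 genes in IR against sham, 1815 in IPO against IR and 15 in IPO against sham. Such a fit has fewer libraries to estimate the spread. In IR against sham it also leaves out IPO, whose median SD within the group was 0.144 on the log2 scale, against 0.182 in sham and 0.232 in IR. The calls of the joint fit may thus rest on a smaller spread than that of the 2 groups compared. The description number as a term left 6 genes in IR against sham, where only sham replicate 2 shares the number of the IR libraries. An estimated correlation called 0 lists in IR against sham, 0 in IPO against IR and 0 in IPO against sham. Leaving out a library gave 310 (sham replicate 2) to 1361 (sham replicate 3) genes in IR against sham, 1085 (IPO replicate 1) to 2231 (sham replicate 3) in IPO against IR, and 1 (sham replicate 2) to 26 (IR replicate 1) in IPO against sham. It gave 8 (IR replicate 1) to 16 (sham replicate 3), 11 to 14 and 3 (IPO replicate 3) to 11 (sham replicate 3) lists, and 285 (sham replicate 1) to 999 (sham replicate 3) opposite changes. For loci it gave 255 (sham replicate 2) to 916 (sham replicate 3), 627 (IPO replicate 1) to 1272 (sham replicate 3), and 0 (sham replicate 1) to 8 (sham replicate 3). The cause of these shifts was not tested.

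Of called named genes, 5 of 68 in IR against sham, 65 of 98 in IPO against IR and 0 of 17 in IPO against sham kept the call throughout, and none of these genes reversed its sign. In IR against sham these were Fosb, Cyr61, Nr4a1, Cyp2b10 and Ier2, and all 63 others lost the call with the description number as a term. Apart from the estimated correlation, 5 of 12, 9 of 14 and 2 of 9 lists kept theirs. Calls also ended with a mean of at least 5 FPKM for neutrophil (0.059), p53 (0.191) and stellate (0.308) lists in IR against sham and interferon (0.406) in IPO against sham, and with the description number for Kupffer (0.0899), neutrophil (0.0753) and sinusoidal (0.0776) lists. They ended too with a replicate block for secreted proteins in IPO against sham (0.0502) and metallothioneins in IPO against IR (0.0544), and without a filter for cell cycle genes (0.429). Medians that shrank over 1.5 times where a call ended were, with a mean of at least 5 FPKM, p53 (0.06) and stellate (0.08) in IR against sham and interferon (0.29) in IPO against sham. With quantile normalization the mitochondrial median was 0.11 in IPO against IR and 0.07 in IPO against sham, and with the description number the sinusoidal median was 0.07 in IR against sham. In IR against sham the p53 median was 0.07 without IR replicate 3. In IPO against IR the sinusoidal median was -0.28 and the erythroid -0.51 without IR replicate 3, and the mitochondrial 0.16 without IR replicate 1. In IPO against sham the medians were 0.36 for cell cycle and 0.05 for secreted proteins without sham replicate 1, 0.30 for cholesterol and 0.36 for monocyte lists without sham replicate 2, 0.33 for cholesterol without IPO replicate 1, and 0.30 for monocytes without IPO replicate 2. The median changed sign for the Kupffer list without IR replicate 3 and the cell cycle list without a filter. The share of called genes that rose in IR against sham was 33.5%, and 41.9% and 39.9% with median-of-ratios scaling and quantile normalization. Pseudocounts of 0.1 and 1, no filter, scalings and robust estimation kept gene counts within 1.5 times.

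List calls were also gained. In IR against sham 15 lists were called with the description number as a term, which added cholesterol (1.8e-05), gluconeogenesis (0.000697), erythroid (0.00629), bile acid (0.0149), coagulation (0.0159) and lipogenesis (0.0287). A pseudocount of 1 added gluconeogenesis and ribosomal lists (both 0.0496), and quantile normalization added the same lists (0.0473 and 0.00245). Leaving out a library added erythroid (0.00293, sham replicate 1; 0.0277, IR replicate 2), heat shock (0.0336, sham replicate 2) and interferon (0.019, IR replicate 2) lists, and without IR replicate 3 bile acid (0.0203), gluconeogenesis (0.0202), mitochondrial (0.0416) and ribosomal (0.0286) lists. Without sham replicate 3 it added cholesterol, gluconeogenesis, bile acid, lipogenesis, ribosomal and coagulation lists. In IPO against IR gains were monocyte (0.0399, no filter; 0.0243, without IR replicate 3; 0.049, without IPO replicate 1), stellate (0.028, without IR replicate 1), Kupffer (0.00251, without IR replicate 2) and interferon (0.00224, without IR replicate 3) lists. In IPO against sham they were gluconeogenesis (0.0435 and 0.00214, without sham replicates 1 and 2), pericentral (0.0284, without sham replicate 2), acute phase (0.0343) and unfolded protein (0.0141, without sham replicate 3) lists, and ribosomal (0.022) and neutrophil (0.0341) lists without IPO replicate 1.

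Some medians moved over 1.5 times while the call was kept. In IR against sham these were clock (0.37 without sham replicate 1, 0.92 without sham replicate 3), secreted proteins (0.11 without sham replicate 1), sinusoidal (0.18 without sham replicate 3, 0.19 without IR replicate 3), Kupffer (0.92 without IR replicate 2), stellate (0.34 without IR replicate 3) and pericentral (0.43 with a mean of at least 5 FPKM). With the description number they were fatty acid oxidation (0.16) and periportal (0.59). In IPO against IR they were ribosomal (0.16) and neutrophil (0.82), without IR replicate 1. In IPO against sham they were heat shock (-0.58 and -0.19 without sham replicates 1 and 2), metallothionein (0.30 and 0.08 without sham replicates 1 and 3, 0.12 without IPO replicate 1) and monocyte (0.40, no filter) lists, and without sham replicate 3 cell cycle (1.02), cholesterol (1.04) and secreted proteins (0.15). Count models were not run since the tables hold no counts.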

Other observations

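The limma tests below were set in advance, and only the choice of Prox1 and Foxa2 for this paragraph was made after the result was seen. Among 19 hepatocyte transcription factors, whose list was not called (camera adjusted p = 0.984 in IR against sham and 0.698 in IPO against IR), 4 fell and 1 rose in IR, and 6 fell and 3 rose in IPO against IR. The 3 that rose were Onecut1, Prox1 and Foxa2. Prox1 fell from 32.3 ± 2.70 FPKM (SD, n = 3) in sham to 13.6 ± 3.36 in IR (log2 fold change -1.25, SE 0.20, limma adjusted p = 0.00662) and rose to 24.4 ± 4.50 in IPO (0.84, SE 0.20, adjusted p = 0.0169). Foxa2 fell from 8.83 ± 1.46 to 4.52 ± 1.86 FPKM (log2 fold change -0.95, SE 0.25, adjusted p = 0.0434) and rose to 9.17 ± 1.44 in IPO (1.00, SE 0.25, adjusted p = 0.0223). With the description number as a term the limma adjusted p of Prox1 in IR against sham was 0.173, and Foxa2 was not called either.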
